A study of Neurospora crassa with 3 samples.

How the data were processed

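Poly-A-selected RNA of Neurospora crassa was measured in 3 samples, each a genotype with 2 sequenced libraries, so 6 libraries in all. The labels name the genotypes H3G34R, set-2 ash1(Y888F) and set-2 H3G34R, and the series' design text gives strains N5247 and N5248 for the first, N6266 and N6267 for the second and N6777 for the last. Each library was taken as 1 replicate, n = 2 per genotype. The 2 libraries came from different strains for H3G34R and for set-2 ash1(Y888F), so their spread includes differences between strains. For set-2 H3G34R both came from a single strain, and nothing says that they came from separate cultures. The p-values measure only the spread between these libraries, which may be technical in the last genotype. The wild-type libraries named by the submitters belong to other series and were not used here.

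The authors deposited 1 table of raw read counts per library, made with STAR 2.6.0 per the submitters' processing notes; the genome build and the annotation are not given in the sources used here. Each table holds 3 count columns, 1 for both strands together and 1 for each strand, and 4 lines of reads not assigned to a gene, which stayed out of library sizes and tests. The kit was stranded per the labels' protocols, and the strand column with more gene-assigned reads in every library was taken as sense and the other as antisense. The authors also deposited, for each genotype, a comparison with wild type made with DESeq2 1.18.1 per the submitters' processing notes. Its columns carry no header and were identified from the values. They are, from the authors, the mean normalised signal per gene (counts divided by size factors), the log2 fold change of mutant over wild type, its standard error, a Wald score, and a p-value with its adjusted form. Which strand column the authors tested is not stated; fitted means came closest to the deposited means with the column for both strands, with a median absolute residual of 0.00145, 0.00251 and 0.00132 on the log2 scale for the H3G34R, set-2 ash1(Y888F) and set-2 H3G34R tables, against 0.00708, 0.0120 and 0.00930 with the sense column. Those fits used genes with a mean count of at least 100 and an absolute log2 fold change of at most 3, and implied 2.02, 2.22 and 2.04 wild-type libraries. The level of each gene in the wild type behind a table was then derived from the deposited mean and fold change, taking equal numbers of mutant and wild-type libraries. Log2 differences between derived wild types were centred on their median over 6148 genes. Those genes had a mean count over 50 and an absolute log2 fold change under 3 in all 3 tables. Derived values of single genes and lists are given without these limits.

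Depth differed little between libraries. Sense reads in genes numbered 9.41 and 9.83 M (1e6 reads) in the H3G34R libraries, 8.43 and 7.52 M in those labelled set-2 ash1(Y888F), and 9.41 and 8.62 M in those labelled set-2 H3G34R, of 11.3, 12.0, 10.2, 8.85, 12.2 and 10.4 M reads in the same order. Antisense reads numbered 0.295 to 0.341 M. Reads outside annotated genes took 10.0%, 11.6%, 9.96%, 9.16%, 16.1% and 11.3% of reads, reads at several places 2.27% to 5.32%, unmapped reads 1.31% to 4.23% and ambiguous reads 0.0956% to 0.152%. The set-2 H3G34R libraries stood apart in mapping. Their unmapped reads were 1.31% and 1.61%, against 3.03% to 4.23% in the other libraries. Their reads at several places were 5.32% and 4.09%, against 2.27% to 3.55%. The 10 genes with the most reads held 7.56% to 10.7% of sense reads, and 8879 to 9241 genes had reads. Intervals and floors in the text cover counting error only, since the reads carry no molecular identifiers. Where all libraries of a group had 0 counts, a fold is a lower bound computed against a floor of 3 counts per library.

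Sense counts were tested with edgeR 4.0.16 (glmQLFit and glmQLFTest, TMM normalisation, filterByExpr by genotype), with all 6 libraries in 1 fit without covariates, two-sided, and Benjamini-Hochberg adjustment at 0.05. The 3 genotypes share an estimate of the spread because 2 libraries against 2 leave few degrees of freedom. Levels are CPM on the TMM-effective library size. Gene lists were tested with camera in limma 3.58.1 on log-CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over the lists of a comparison, and again with a correlation estimated per list. Antisense counts were tested in the same way with the sense effective library sizes. The antisense share of a library is antisense reads over antisense plus sense reads in genes, compared by an exact two-sided permutation test between the 4 libraries labelled set-2 and the other 2. Enrichment at chromosome ends was tested with Fisher's exact test, two-sided, with 95% intervals. Software was R 4.3.3, DESeq2 1.42.0 as an alternative test, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

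Gene symbols came from a reference table of assembly NC12, in which 9729 of the 9730 counted genes were found by locus tag and 1118 have a symbol; other genes are given by locus tag. No coordinates are printed, since the build behind the counts is not named. The planned windows of 100, 200 and 300 kb from chromosome ends and the rule of 500 bp between opposing genes were therefore not run. In their place stand the outermost 50 genes at each end of the 7 chromosomes, and the 7286 genes whose column for both strands equals sense plus antisense reads in every library, which thus share no reads with an opposing gene.

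Comparisons, tests, alternatives, 10 gene lists and the rule for named genes were fixed before the data were examined. That rule takes the target genes set-2, ash1 and hH3 first. It then takes, per comparison, the 10 largest rises and 10 largest falls among genes that passed with a mean of at least 5 CPM in the higher genotype and no overlap between libraries, list members that passed, and from each deposited table the 5 largest rises and falls with an adjusted p under 0.05 and a mean normalised count of at least 20. The lists cover histone methylation machinery, histones, clock and light, conidiation, sexual development and mating, plant cell wall degradation and carbon, the quinate cluster, nitrogen, phosphorus and sulphur supply, stress and chaperones, and RNA interference with DNA repair. Of their members, 2 were dropped because the reference gives their locus another symbol: the locus listed as ash1, NCU01932, is set-3 there, and the locus listed as npf is cac-3. The lists planned by product text were not formed, since the reference holds no such text. In their place, 5 lists by symbol pattern (cytosolic ribosomal proteins, glycoside hydrolases, respiratory complex I, proteasome and polyketide synthases) were formed after the annotation had been seen, which brings list entries to 274. Of these genes, 10 stand both among plant cell wall and carbon genes and among glycoside hydrolases, so these 2 lists are not independent. Lists with under 5 tested genes would have been counted only. Genes named for their antisense reads, the symbol genes among those with at least 5 antisense CPM, were chosen after their values had been seen.

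The pipeline was tested on simulated counts with known changes, drawn from the mean of each gene over all 6 libraries and the real library sizes. At each size of change 58 to 67 genes in the fit were changed. The real comparisons called 3264, 5286 and 4435 genes, so recovery and false calls in them may differ from those simulated. On sense counts, 4-fold changes were recovered for 92.4% of changed genes for set-2 H3G34R against set-2 ash1(Y888F) (8462 genes in the fit), 95.4% for set-2 H3G34R against H3G34R (8456 genes) and 86.4% for set-2 ash1(Y888F) against H3G34R (8449 genes). The shares were 49.3%, 58.2% and 50.7% for 2-fold changes and 8.96%, 4.55% and 7.58% for 1.5-fold changes, with 11, 8 and 13 false calls. Genes recovered at 1.5-fold, 2-fold and 4-fold numbered 6, 33 and 61, then 3, 39 and 62, then 5, 34 and 57. As a share of all calls, false calls thus exceeded the adjustment threshold of 0.05 in each of these comparisons. On antisense counts, 4-fold changes were recovered for 84.4%, 90% and 79.3% in fits of 3878, 3897 and 3865 genes, with 7, 3 and 5 false calls. The shares were 31.1%, 26.2% and 29.5% for 2-fold changes and 3.17%, 11.3% and 6.90% for 1.5-fold changes. Antisense false calls exceeded the same threshold in the first and last comparison, but not for set-2 H3G34R against H3G34R. Sets against a shared control were simulated with 10 draws of unchanged groups.

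Alternatives tried were DESeq2 size factors, DESeq2's own test, no filter on low counts, the column for both strands, a fit of only the 2 genotypes compared, glmTreat against a 1.5-fold change, leaving out each library in turn, fry in place of camera, TMM of the antisense counts, other numbers of genes from chromosome ends and other summaries of the antisense share. When 1 library was left out, the remaining library of that genotype was assumed to vary like the others. Reads that fell at several places in the genome and genes on no chromosome were left out.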

Results

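Poly-A RNA of Neurospora crassa, a filamentous fungus, was sequenced from cultures grown for 18 h at 32 °C in shaken liquid medium. The 6 stranded libraries represent 3 genotypes with 2 libraries each. H3G34R strains (N5247 and N5248) carry a glycine-to-arginine change in histone H3. The genotype labelled set-2 ash1(Y888F) (N6266 and N6267) carries a change that inactivates ASH1, a histone H3K36 methyltransferase, and is described as a deletion of set-2, which encodes the other H3K36 methyltransferase of this fungus. The genotype labelled set-2 H3G34R (N6777) is described as joining the H3 change to the set-2 deletion. Libraries held 7.52 to 9.83 M sense reads in genes (M, 1e6 reads). Over genes, log2(CPM + 1) correlated between the 2 libraries of a genotype with r = 0.994 for H3G34R, 0.987 for set-2 ash1(Y888F) and 0.995 for set-2 H3G34R, and between genotypes with r from 0.886 to 0.961; genes are not independent replicates. The 2 libraries of a genotype differed by more than read-counting noise, with a chi-square per degree of freedom of 11.1, 36.6 and 11.9, which 2 preparations of 1 culture could also exceed. Each library was counted as a replicate because the authors deposited a separate table of counts for it.

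The target gene set-2 (NCU00269) had reads in every library, including those of strains described as deletions. The labels themselves name set-2 without the word deletion. Sense reads numbered 322 and 252 in the H3G34R libraries, 171 and 123 in those labelled set-2 ash1(Y888F), and 299 and 269 in those labelled set-2 H3G34R. Levels were 27.6 ± 4.90, 20.7 ± 3.48 and 30.2 ± 0.00453 CPM (SD, n = 2 each), while a count of 0 would have allowed at most 0.287 to 0.446 CPM. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, set-2 H3G34R differed from set-2 ash1(Y888F) by a log2 value of 0.54 (SE 0.190, adjusted p = 0.0632) and from H3G34R by 0.13 (adjusted p = 0.562), and set-2 ash1(Y888F) from H3G34R by −0.41 (adjusted p = 0.110). Leaving out set-2 ash1(Y888F) replicate 1 brought the first and the last past the threshold (0.72, adjusted p = 0.0349, and −0.59, adjusted p = 0.0464), and leaving out H3G34R replicate 2 turned the other to −0.04 (adjusted p = 0.883). Gene counts do not show which part of the gene the reads came from. Because set-2 reads go against the description as a deletion, the groups are called by their labels throughout. Every direction given for set-2 rests on those labels.

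The locus listed beforehand as ash1 (NCU01932, set-3 in the reference) was at 148 ± 0.395 CPM in H3G34R, 90.9 ± 1.06 in set-2 ash1(Y888F) and 71.5 ± 0.0577 in set-2 H3G34R (SD, n = 2 each). It was lower in both genotypes labelled set-2 than in H3G34R, by log2 values of −0.71 (SE 0.0945, adjusted p = 0.00131) and −1.05 (SE 0.0949, adjusted p = 2.12e-04). Between the genotypes labelled set-2 it differed by −0.35 (adjusted p = 0.0288), a call lost without any 1 of 5 libraries, at adjusted p = 0.0680 and 0.0679 without H3G34R replicates 1 and 2, 0.0526 without set-2 ash1(Y888F) replicate 1, and 0.111 and 0.121 without set-2 H3G34R replicates 1 and 2. The histone H3 gene hH3 (NCU01635) was at 1745 ± 48.3, 1685 ± 169 and 1251 ± 48.3 CPM. Its level in set-2 H3G34R differed from set-2 ash1(Y888F) by −0.43 (adjusted p = 0.0372) and from H3G34R by −0.48 (adjusted p = 0.0155), and set-2 ash1(Y888F) from H3G34R by −0.05 (adjusted p = 0.757). The call against set-2 ash1(Y888F) was lost without H3G34R replicate 1 or 2 (0.0811 each), set-2 ash1(Y888F) replicate 1 (0.0651) or set-2 H3G34R replicate 1 (0.129) or 2 (0.191). That against H3G34R was lost without H3G34R replicate 1 (0.0658) or 2 (0.0883), or set-2 H3G34R replicate 1 (0.0689) or 2 (0.105). The difference between set-2 ash1(Y888F) and H3G34R turned to 0.05 without set-2 ash1(Y888F) replicate 2 (adjusted p = 0.722).

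**Figure D1:**
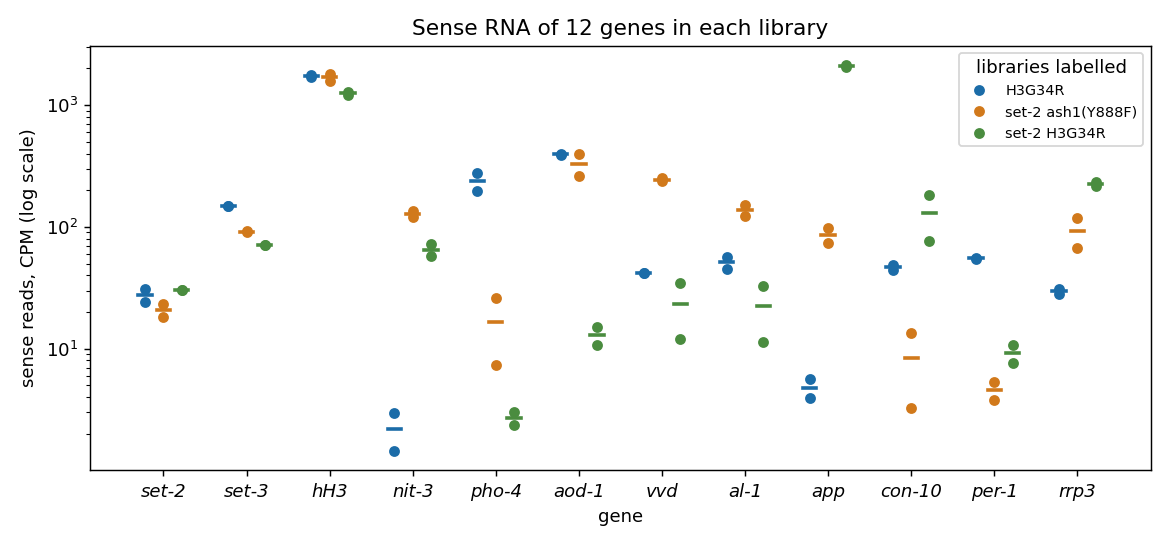
Sense CPM on a log axis for 12 genes in each of the 6 libraries, with a line at the mean of the 2 libraries of a genotype. set-2 lies between 18.3 and 31.0 CPM in all libraries, whereas app lies at a mean of 4.80 in H3G34R and 2085 in set-2 H3G34R.

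The comparison of set-2 H3G34R with set-2 ash1(Y888F) asks whether the change in H3 and the change in ASH1 differ in RNA. Both genotypes carry the set-2 label. The strains differ too, and set-2 H3G34R is a single strain. Strain and any library batch were not separated from genotype, so no difference below can be assigned to H3 or ASH1. Of 12 clock and light genes, 5 were lower in the libraries labelled set-2 H3G34R, among them the blue-light photoreceptor gene vvd (NCU03967), at 23.2 ± 16.0 against 243 ± 9.45 CPM, and the cryptochrome gene cry (NCU00582), at 10.2 ± 3.99 against 100.2 ± 13 CPM (SD, n = 2 each). The alternative oxidase gene aod-1 (NCU07953) was also lower, at 12.9 ± 2.92 against 327 ± 95.6 CPM, as was am (NCU01195), which encodes glutamate dehydrogenase, at 413 ± 48.7 against 1644 ± 723 CPM. Higher in set-2 H3G34R were the conidiation gene con-10 (NCU07325), at 129 ± 75.1 against 8.38 ± 7.26 CPM, and app (NCU04533), at 2085 ± 53.4 against 86.2 ± 17.1 CPM.

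In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 3264 of 8561 tested genes (38.1%) differed between these genotypes, 1562 higher and 1702 lower in set-2 H3G34R. At least 4-fold differences were found for 226 higher and 198 lower genes. Only 1551 and 1388 genes passed without set-2 H3G34R replicate 1 and replicate 2, and 1131 passed against a minimum of 1.5-fold. Among the 20 genes named by size, NCU09968 and NCU09969 had no reads in either set-2 ash1(Y888F) library and were at least 284-fold and 20.6-fold higher in set-2 H3G34R, at 121 ± 4.25 and 8.77 ± 0.131 CPM. The gene app was higher by a log2 value of 4.60 (SE 0.212, adjusted p = 8.71e-05) and gh10-4, a glycoside hydrolase gene, by 4.59 (SE 0.501, adjusted p = 0.00159). NCU01402 was at 1.98 ± 0.374 against 4206 ± 956 CPM, a log2 value of −11.05 (SE 0.294, adjusted p = 3.81e-05), and NCU11365 at 23.6 ± 3.87 against 1428 ± 46.6 CPM, −5.92 (SE 0.176, adjusted p = 3.96e-05). The L-amino acid oxidase gene lao was at 7.22 ± 0.0605 against 291 ± 138 CPM, −5.33 (SE 0.512, adjusted p = 0.00108).

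Of 12 clock and light genes, 1 was higher, 5 were lower and 6 did not pass, and 6 passed when adjusted over the list alone. The largest falls were vvd (−3.39, adjusted p = 0.00244), cry (−3.30, adjusted p = 6.80e-04) and al-1, a carotenoid synthesis gene (−2.63, adjusted p = 0.00519). Of 15 genes of nitrogen, phosphorus and sulphur supply, none was higher, 8 were lower and 7 did not pass (8 adjusted over the list alone). Here am was at −1.99 (adjusted p = 0.00411) and nmr, a regulator of nitrogen metabolism, at −0.71 (adjusted p = 0.00361). Markers of conidia and aerial hyphae were higher for 6 of 13 genes, lower for 1 and not past the test for 6 (8 adjusted over the list alone), led by con-10 (3.96, adjusted p = 0.00479). Sexual development and mating genes were higher for 6 of 11, with 5 not past the test (6 adjusted over the list alone), among them the mating-type genes matA-2 (2.10, adjusted p = 0.00802) and matA-3 (1.47, adjusted p = 0.00678). In the quinate cluster 4 of 6 genes were higher and 2 did not pass (4 adjusted over the list alone), including the regulators qa-1F (1.30, adjusted p = 0.00561) and qa-1S (1.09, adjusted p = 0.00503). Each of these 5 lists passed camera at an adjusted p of 0.0363, the first 2 towards lower and the others towards higher values. With an estimated correlation the calls were lost, at adjusted p = 0.623 with an estimated correlation for clock and light and adjusted p = 0.618 with an estimated correlation for the other 4.

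The lists formed by symbol, after the annotation had been seen, gave 3 more calls. All 7 cytosolic ribosomal protein genes were lower (camera adjusted p = 0.00481; adjusted p = 0.618 with an estimated correlation). Here crp-2 was at −0.92 (adjusted p = 0.00429). Of 30 proteasome genes, 6 were lower and 24 did not pass (camera adjusted p = 0.0106, and adjusted p = 0.542 with an estimated correlation), led by rpn-4 (−1.43, adjusted p = 0.00271). Adjusted over the proteasome list alone, only 3 passed. Of 72 glycoside hydrolase genes, 21 were higher, 9 lower and 42 not past the test (camera adjusted p = 0.0363; adjusted p = 0.618 with an estimated correlation). Here gh76-3 was at 1.96 (adjusted p = 0.00447) and gh2-2 at 1.61 (adjusted p = 0.00478). The lists at 0.0363 also depended on single libraries. Without H3G34R replicate 1 all 6 were lost, at 0.0536 for clock and light and for nutrient supply and 0.0539 for the other 4. Without set-2 ash1(Y888F) replicate 1 the values were 0.0661 for clock and light, conidiation and sexual development, 0.0795 for the quinate cluster and 0.0984 for glycoside hydrolases, and without its replicate 2 clock and light was at 0.0568. Without set-2 H3G34R replicate 1 they were 0.0527 for clock and light and for sexual development, 0.0695 for nutrient supply, 0.0788 for the quinate cluster and 0.101 for glycoside hydrolases, and without its replicate 2 conidiation was at 0.0636.

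The remaining lists did not pass camera in this comparison. Stress and chaperone genes were lower for 5 of 12, with 7 not past the test (5 adjusted over the list alone; camera adjusted p = 0.147), among them aod-1 (−4.67, adjusted p = 2.17e-04) and hsp60, a mitochondrial chaperone gene, at 101 ± 30.8 against 295 ± 69.6 CPM. Of 7 histone genes 3 were lower and 4 did not pass (3 adjusted over the list alone; camera adjusted p = 0.130). The histone methylation list had 2 of 15 genes lower and 13 not past the test (0 adjusted over the list alone; camera adjusted p = 0.981). Plant cell wall and carbon genes were higher for 2, lower for 3 and not past the test for 14 of 19 (4 adjusted over the list alone; camera adjusted p = 0.529). Here the cellulase gene cbh-1 was at 16.2 ± 1.13 against 5.28 ± 0.941 CPM and gh61-2 at 3.47 ± 0.943 against 25.1 ± 7.10 CPM. RNA interference and DNA repair genes were higher for 3, lower for 1 and not past the test for 6 of 10 (4 adjusted over the list alone; camera adjusted p = 0.824), including qde-1, an RNA-dependent RNA polymerase gene (0.85, adjusted p = 0.00697), and mus-51, a Ku protein gene (−0.71, adjusted p = 0.00463). Among 29 complex I genes 1 was lower and 28 did not pass (0 adjusted over the list alone, camera adjusted p = 0.566). Among 6 polyketide synthase genes 2 were lower and 4 did not pass (camera adjusted p = 0.707). Adjusted over the polyketide synthase list alone, 5 passed, 2 higher and 3 lower. Signs differed for the methylation list, with a median of 0.0129, a mean of 0.0122 and a test towards lower values, and for RNA interference, with a median of −0.05, a mean of 0.13 and a test towards higher values.

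**Figure D2:**
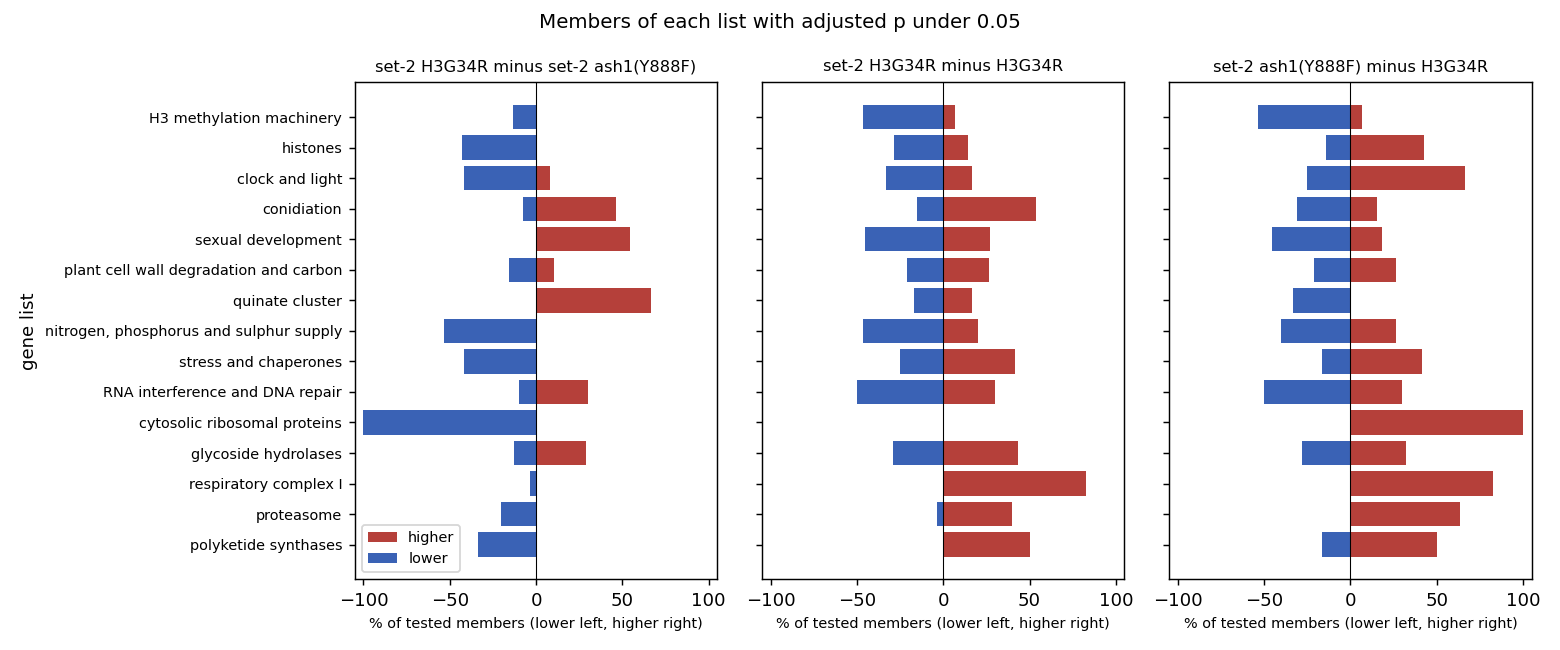
Share of tested members of 15 gene lists that were higher (to the right) or lower (to the left), in percent, in each of the 3 comparisons. In complex I, 24 of 29 members were higher in each genotype labelled set-2 than in H3G34R, against none between the genotypes labelled set-2. Both comparisons with H3G34R use the same H3G34R libraries, so they are not independent.

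By their labels, set-2 H3G34R and H3G34R differ in set-2, which is described as deleted in the former. Reads of set-2 at 30.2 ± 0.00453 against 27.6 ± 4.90 CPM go against that description. The strains differ too, so no difference below can be assigned to a deletion. The phosphate transporter genes pho-4 (NCU09564) and pho-5 (NCU08325) were lower, at 2.69 ± 0.475 against 237 ± 57.2 CPM and 0.898 ± 0.158 against 78.9 ± 6.33 CPM (SD, n = 2 each). The nitrate reductase gene nit-3 (NCU05298) was higher, at 65.2 ± 10.1 against 2.21 ± 1.07 CPM. Of 29 genes of respiratory complex I, 24 were higher, with nuo18.4 (NCU00484) at 248 ± 5.36 against 101 ± 11.3 CPM. The alternative oxidase gene aod-1 was lower, at 12.9 ± 2.92 against 396 ± 5.67 CPM, as was the mitochondrial chaperone gene hsp60, at 101 ± 30.8 against 509.8 ± 4.10 CPM.

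By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 5286 of 8561 genes (61.7%) differed, 2626 higher and 2660 lower in set-2 H3G34R, with at least 4-fold differences for 596 and 601. Against a minimum of 1.5-fold, 3079 genes passed. Among the 20 genes named by size, app was higher by a log2 value of 8.76 (SE 0.263, adjusted p = 7.11e-06), NCU02932 by 9.94 (SE 0.265, adjusted p = 7.11e-06), at 392 ± 15.1 against 0.383 ± 0.270 CPM, and NCU00995 by 6.91 (SE 0.150, adjusted p = 7.11e-06). NCU04706 and NCU06888 had no reads in either set-2 H3G34R library and were at least 284-fold and 278-fold lower than in H3G34R, where they stood at 90.9 ± 0.798 and 88.8 ± 9.71 CPM. The kinase gene stk-35 was at 0.0561 ± 0.0794 against 125 ± 4.55 CPM, with a single read in set-2 H3G34R (adjusted p = 2.74e-05), and NCU06590 at 0.942 ± 0.380 against 713 ± 11.4 CPM, a log2 value of −9.52 (SE 0.225, adjusted p = 7.11e-06).

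Complex I was the one list that passed camera in this comparison, and it was formed by symbol after the annotation had been seen. Of its 29 genes, 24 were higher and 5 did not pass (camera adjusted p = 7.75e-06; adjusted p = 0.936 with an estimated correlation), with nuo14.8 at 1.42 (adjusted p = 2.54e-04), nuo18.4 at 1.30 (adjusted p = 2.25e-04) and nuo6.6 at 1.29 (adjusted p = 5.03e-04). Nitrogen, phosphorus and sulphur genes were higher for 3, lower for 7 and not past the test for 5 of 15 (10 adjusted over the list alone; camera adjusted p = 0.358), including pho-4 (−6.45, adjusted p = 2.28e-04), pho-5 (−6.43, adjusted p = 1.98e-05), nit-3 (4.87, adjusted p = 5.08e-05) and am (−2.60, adjusted p = 5.71e-04). The histone methylation list had 1 gene higher, 7 lower and 7 not past the test (8 adjusted over the list alone; camera adjusted p = 0.178). Its members included the histone deacetylase gene hda-1 (−1.32, adjusted p = 2.21e-04), the H3K4 methyltransferase gene set-1 (−0.94, adjusted p = 8.33e-04) and the H3K27 methyltransferase gene set-7, at 26.4 against 45.5 CPM. Among RNA interference and DNA repair genes 3 were higher, 5 lower and 2 not past the test (8 adjusted over the list alone; camera adjusted p = 0.820). Here the Argonaute gene qde-2 was at 408 ± 9.84 against 186 ± 0.461 CPM, rrp3 at 225 ± 14 against 29.6 ± 2.13 CPM, the helicase gene qde-3 at 36.7 ± 5.60 against 102 ± 0.940 CPM and mei-3 at 25.7 ± 0.259 against 71.3 ± 3.17 CPM.

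Markers of conidia and aerial hyphae were higher for 7 of 13 genes, lower for 2 and not past the test for 4 (9 adjusted over the list alone; camera adjusted p = 0.514). Here the hydrophobin gene eas was at 411 ± 349 against 13.5 ± 8.82 CPM, ccg-14 at 4153 ± 839 against 659.6 ± 26.9 CPM and rca-1 at 57.2 ± 19.3 against 11.9 ± 0.0644 CPM. Sexual development genes were higher for 3, lower for 5 and not past the test for 3 of 11 (8 adjusted over the list alone; camera adjusted p = 0.604). Among them were the pheromone gene ccg-4 (−4.02, adjusted p = 8.36e-05), the perithecial pigment gene per-1 (−2.57, adjusted p = 1.78e-04) and asd-1 (3.02, adjusted p = 2.89e-04). Clock and light genes were higher for 2, lower for 4 and not past the test for 6 of 12 (5 adjusted over the list alone; camera adjusted p = 0.748). Here the carotenoid gene al-2 was at 214 ± 35.7 against 31.5 ± 2.68 CPM and the light receptor subunit gene wc-2 at 111 ± 3.70 against 41.2 ± 1.41 CPM. The clock gene frh was lower (−1.17, adjusted p = 7.91e-04). Stress genes were higher for 5, lower for 3 and not past the test for 4 of 12 (8 adjusted over the list alone; camera adjusted p = 0.917). Plant cell wall and carbon genes were higher for 5, lower for 4 and not past the test for 10 of 19 (9 adjusted over the list alone; camera adjusted p = 0.748). Here cbh-1 was at 2.07 (adjusted p = 3.60e-04) and the regulator clr-2 at −2.23 (adjusted p = 0.00147). Glycoside hydrolase genes were higher for 31, lower for 21 and not past the test for 20 of 72 (camera adjusted p = 0.276), including gh61-6 (3.77, adjusted p = 9.97e-05), gh35-1 (3.23, adjusted p = 6.47e-04) and gh18-1 (−5.13, adjusted p = 1.50e-04).

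None of the remaining lists passed camera. In histones 1 gene was higher, 2 lower and 4 not past the test (3 adjusted over the list alone; camera adjusted p = 0.868). Here the linker histone gene hH1 was at 457 ± 0.906 against 234 ± 24.7 CPM. In the quinate cluster 1 gene was higher, 1 lower and 4 not past the test (2 adjusted over the list alone; camera adjusted p = 0.868). No ribosomal protein gene of 7 passed (camera adjusted p = 0.604). Of 30 proteasome genes 12 were higher, 1 was lower and 17 did not pass (camera adjusted p = 0.276). Here pca-5 was at 0.72 (adjusted p = 0.00193) and rpn-4 at −1.90 (adjusted p = 3.01e-04). Polyketide synthase genes were higher for 3 of 6, with 3 not past the test (camera adjusted p = 0.276). Median, mean and test differed in sign for stress, with a median of 0.04, a mean of −0.17 and a test towards lower values, and for RNA interference, with a median of −0.26, a mean of 0.00447 and a test towards lower values.

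The genotypes labelled set-2 ash1(Y888F) and H3G34R differ, by their labels, in set-2 and in which of ASH1 or H3 is changed. Their strains differ too. The H3G34R libraries are the same as in the comparison above, so results found in both comparisons are not independent. In set-2 ash1(Y888F) 24 of 29 complex I genes, 19 of 30 proteasome genes and all 7 cytosolic ribosomal protein genes were higher. Of complex I, nuo14.8 (NCU00418) was at 261 ± 36.2 against 86.8 ± 7 CPM (SD, n = 2 each). The nitrate reductase gene nit-3 was also higher, at 128 ± 9.93 against 2.21 ± 1.07 CPM, as was cry, at 100.2 ± 13 against 13.8 ± 1.15 CPM. The pheromone gene ccg-4 and the perithecial pigment gene per-1 were lower, at 7.27 ± 3.14 against 88.5 ± 0.676 CPM and 4.57 ± 1.10 against 55.0 ± 0.637 CPM.

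In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment 4435 of 8561 genes (51.8%) differed, 2249 higher and 2186 lower in set-2 ash1(Y888F), with at least 4-fold differences for 423 and 559. The count was 2754 without H3G34R replicate 1 and 2248 against a minimum of 1.5-fold. NCU01402 was at 4206 ± 956 against 8.40 ± 0.657 CPM, a log2 value of 8.96 (SE 0.262, adjusted p = 6.71e-06), NCU00995 at 719.7 ± 17.2 against 2.50 ± 0.122 CPM, 8.16 (SE 0.156, adjusted p = 4.06e-06), and NCU11365 at 1428 ± 46.6 against 21.8 ± 1.99 CPM, 6.03 (SE 0.177, adjusted p = 6.71e-06). No read of stk-35, NCU04706 or NCU09968 was found in the set-2 ash1(Y888F) libraries, which puts them at least 294-fold, 213-fold and 168-fold lower than in H3G34R.

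Of 29 complex I genes 24 were higher and 5 did not pass (camera adjusted p = 2.75e-07; adjusted p = 0.554 with an estimated correlation), led by nuo14.8 (1.59, adjusted p = 2.50e-04). Of 30 proteasome genes 19 were higher and 11 did not pass (camera adjusted p = 6.17e-04; adjusted p = 0.312 with an estimated correlation). Here pca-5 was at 0.89 (adjusted p = 0.00123) and rpn-10 at 0.72 (adjusted p = 0.00190). All 7 ribosomal protein genes were higher (camera adjusted p = 0.0241; adjusted p = 0.793 with an estimated correlation). Here crp-5 was at 0.80 (adjusted p = 0.00501). These 3 lists had been formed by symbol. Among the lists fixed beforehand, that of histone methylation passed, towards lower values: 1 gene was higher, 8 were lower and 6 did not pass (11 adjusted over the list alone; camera adjusted p = 0.0241; adjusted p = 0.554 with an estimated correlation). Without set-2 ash1(Y888F) replicate 2 its adjusted p was 0.0697. Members included hda-1 at 41.1 ± 0.761 against 80.6 ± 4.31 CPM, set-1 at 58.2 ± 3.15 against 109.8 ± 12 CPM and chap, a gene of a histone deacetylase complex, at 60.2 ± 15 against 22.7 ± 2.30 CPM.

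Sexual development genes were higher for 2, lower for 5 and not past the test for 4 of 11 (7 adjusted over the list alone; camera adjusted p = 0.133). Here ccg-4 and per-1 were each at −3.59 (adjusted p = 1.36e-04 and 1.05e-04) and matA-3 at −2.99 (adjusted p = 2.25e-04). Clock and light genes were higher for 8, lower for 3 and not past the test for 1 of 12 (11 adjusted over the list alone; camera adjusted p = 0.189), among them cry (2.86, adjusted p = 2.85e-04), al-2 (2.74, adjusted p = 2.41e-04) and vvd (2.55, adjusted p = 0.00258). Markers of conidia and aerial hyphae were higher for 2, lower for 4 and not past the test for 7 of 13 (6 adjusted over the list alone; camera adjusted p = 0.842), including rca-1 (1.38, adjusted p = 0.00522) and con-13 (−3.06, adjusted p = 0.00538). Nitrogen, phosphorus and sulphur genes were higher for 4, lower for 6 and not past the test for 5 of 15 (10 adjusted over the list alone; camera adjusted p = 0.493). Here pho-5 was at 3.09 ± 1.00 against 78.9 ± 6.33 CPM and pho-4 at 16.6 ± 13.2 against 237 ± 57.2 CPM. RNA interference and DNA repair genes were higher for 3, lower for 5 and not past the test for 2 of 10 (8 adjusted over the list alone; camera adjusted p = 0.574). Here qde-2 was at 1.20 (adjusted p = 3.06e-04), mei-3 at −1.16 (adjusted p = 4.74e-04) and qde-1 at −1.29 (adjusted p = 7.91e-04).

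Histone genes were higher for 3, lower for 1 and not past the test for 3 of 7 (5 adjusted over the list alone; camera adjusted p = 0.487). Here hH1 was at 565 ± 62.8 against 234 ± 24.7 CPM. In the quinate cluster 2 genes were lower and 4 did not pass (2 adjusted over the list alone; camera adjusted p = 0.325), these being qa-1S and qa-1F, at 9.74 ± 0.928 against 29.7 ± 1.38 CPM and 5.07 ± 1.03 against 15.3 ± 1.00 CPM. Stress genes were higher for 5, lower for 2 and not past the test for 5 of 12 (7 adjusted over the list alone; camera adjusted p = 0.325). Plant cell wall and carbon genes were higher for 5, lower for 4 and not past the test for 10 of 19 (9 adjusted over the list alone; camera adjusted p = 0.842). Here gh61-5 was at 2.72 (adjusted p = 4.69e-04) and gh5-1 at −3.14 (adjusted p = 8.20e-04). Glycoside hydrolase genes were higher for 23, lower for 20 and not past the test for 29 of 72 (camera adjusted p = 0.842), and polyketide synthase genes higher for 3, lower for 1 and not past the test for 2 of 6 (camera adjusted p = 0.180). Signs differed for conidiation, with a median of 0.22, a mean of −0.12 and a test towards lower values, and for glycoside hydrolases, with a median of −0.02, a mean of −0.18 and a test towards higher values.

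H3K27 methylation of this fungus lies largely near chromosome ends, and the outermost 50 genes at each end were therefore tested as a set of 602 among 8560 placed genes. Genes higher in set-2 H3G34R than in set-2 ash1(Y888F) lay there more often than genes that did not pass, 144 of 1562 (9.22%) against 328 of 5297 (6.19%), an odds ratio of 1.54 (95% interval 1.24 to 1.89, Fisher's exact test, adjusted p = 3.88e-04). This test takes genes as independent in position. Genes at least 4-fold higher in the same comparison formed 29 neighbouring pairs, against a mean of 5.94 in random sets. The p-values may therefore be too small and the interval too narrow. With the outermost 25 genes the odds ratio was 1.43 and the adjusted p 0.0804, and with the outermost 100 genes they were 1.34 and 0.00199. For genes lower in that comparison the odds ratio was 1.25 (adjusted p = 0.111). Against H3G34R it was 1.08 for genes higher in set-2 H3G34R (adjusted p = 0.534) and 1.00 for those lower (adjusted p = 1), the latter turning to 0.897 with the outermost 25 genes, and 1.15 and 1.10 for genes higher and lower in set-2 ash1(Y888F) (adjusted p = 0.362 and 0.534).

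Antisense reads were examined because loss of H3K36 methylation by SET-2 is known to raise such transcripts in yeasts. The antisense share of gene reads was 3.08% and 3.15% in the H3G34R libraries, 3.68% and 3.78% in those labelled set-2 ash1(Y888F), and 3.49% and 3.46% in those labelled set-2 H3G34R. The 4 libraries labelled set-2 averaged 3.60% ± 0.152 (SD, n = 4) against 3.11% ± 0.0442 (SD, n = 2), a difference of 0.487 percentage points. In an exact two-sided permutation test p was 0.0667, the smallest that 15 arrangements can give, so the design cannot pass 0.05. The test takes the 6 libraries as exchangeable, although they are 3 genotypes with 2 libraries each, so its p-values may be too small. The SD of the 4 libraries spans 2 genotypes. The median over genes with at least 100 reads differed by 0.372 percentage points (permutation p = 0.133). Its mean was 0.818% in H3G34R, 1.45% in set-2 ash1(Y888F) and 0.927% in set-2 H3G34R, so most of the difference lay in set-2 ash1(Y888F). Of 3 summaries chosen after seeing the data, the 7286 genes that share no reads with an opposing gene gave 0.218 (permutation p = 0.133), the median of the 500 genes highest in sense reads 0.0988 (p = 0.733), and all genes without the 20 that add most 0.264 (p = 0.0667).

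Antisense reads of stk-28, a kinase gene, stood at 26.4 ± 2.38 CPM in set-2 H3G34R and 15.1 ± 0.331 in set-2 ash1(Y888F) against 0.575 ± 0.404 in H3G34R (SD, n = 2 each), with log2 values of 5.48 and 4.68 (adjusted p = 2.93e-11 and 8.65e-10). Those of rtg2 stood at 18.9 ± 1.97 and 14.96 ± 0.0616 against 0.480 ± 0.133 CPM, and those of the hyphal fusion gene ham-2 at 27.7 ± 3.05 and 14.3 ± 2.02 against 0.863 ± 0.403 CPM. In the other direction, antisense reads of cys-3, a sulphur regulator gene, stood at 9.70 ± 0.726 and 18.4 ± 0.216 against 64.2 ± 9.43 CPM. Antisense reads of set-3 stood at 9.25 ± 1.20 CPM in set-2 ash1(Y888F) against 0.589 ± 0.119 in set-2 H3G34R (−3.95 for set-2 H3G34R minus set-2 ash1(Y888F), adjusted p = 2.88e-07). In H3G34R replicates 1 and 2 they stood at 1.25 and 2.3 CPM, so they were high only in set-2 ash1(Y888F). This is the locus listed beforehand as ash1. If it is ash1, it is the gene changed in that genotype, and an effect of the altered locus itself cannot be told apart. Among these genes rtg2, ham-2 and cys-3 share reads with an opposing gene, so their antisense reads may belong to that gene.

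By edgeR's quasi-likelihood test on antisense counts with Benjamini-Hochberg adjustment and sense library sizes, 1754 of 4299 genes differed between set-2 H3G34R and H3G34R (1138 higher, 616 lower), 1956 between set-2 ash1(Y888F) and H3G34R (1678 higher, 278 lower) and 1611 between the genotypes labelled set-2 (397 higher and 1214 lower in set-2 H3G34R). The split depended on scaling: with TMM of the antisense counts themselves it was 878 higher and 970 lower, 684 and 676, and 737 and 735, since this scaling moved the median log2 value by −0.33, −0.70 and 0.37. In a separate fit of only the genes that share no reads with an opposing gene 997, 1166 and 1059 differed. Between the genotypes labelled set-2 the count was 950 without set-2 ash1(Y888F) replicate 1, and 978 and 997 without set-2 H3G34R replicates 1 and 2. Sense reads also passed for 1072, 1064 and 730 of the genes called, in the same direction for 650, 794 and 616. Both comparisons with H3G34R use the same H3G34R libraries, so their antisense calls are not independent.

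**Figure D3:**
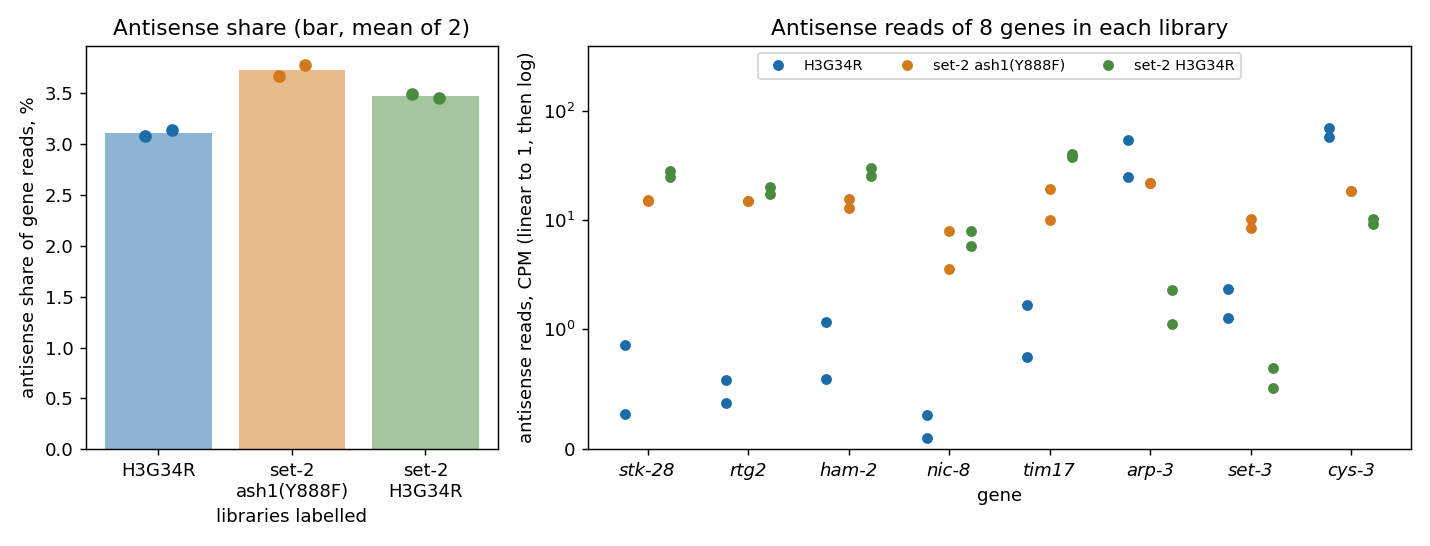
Left, antisense share of gene reads in percent, with bars at the mean of 2 libraries and points for each library; right, antisense CPM of 8 genes per library on an axis that is linear up to 1 and logarithmic above. The shares lie at 3.08% and 3.15% for H3G34R and between 3.46% and 3.78% for the libraries labelled set-2.

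For the comparisons with wild type, only the authors' results were used. The wild-type libraries belong to other series, so genotype and series cannot be told apart in these results. In the authors' deposited table for H3G34R, 6186 of 9596 genes had an adjusted p under 0.05, 3223 higher and 2963 lower than wild type. The authors' deposited table for set-2 H3G34R held 4909 of 9577, 2384 higher and 2525 lower, and the authors' deposited table for set-2 ash1(Y888F) held 1504 of 8718, 944 higher and 560 lower. With at least a 2-fold change the counts in the authors' deposited tables were 3987, 2541 and 1156. For set-2 itself the log2 values in the authors' deposited tables were 1.34 in H3G34R, 1.35 in set-2 H3G34R and −0.01 in set-2 ash1(Y888F), and for hH3 −0.11, −0.74 and −0.44. Locus NCU01932 (set-3) had 0.87, −0.33 and −0.07 in the authors' deposited tables.

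The light-responsive genes vvd and cry were lower in all 3 of the authors' deposited tables, with log2 values for vvd of −6.30 in H3G34R, −6.54 in set-2 H3G34R and −1.51 in set-2 ash1(Y888F), and for cry of −6.67, −6.80 and −1.90. The phosphate genes pho-4 and pho-5 stood at 6.92 and 6.34 in the authors' deposited table for H3G34R, 0.75 and 0.09 in that for set-2 H3G34R and −1.09 and 0.57 in that for set-2 ash1(Y888F). Of the largest rises in the authors' deposited tables, NCU00425 (12.49) and NCU06590 (12.03) led for H3G34R, app (9.02) and NCU09209 (8.07) for set-2 H3G34R, and NCU06413 (6.59) and NCU04697 (6.57) for set-2 ash1(Y888F). The largest falls in the authors' deposited tables were NCU09775 (−11.38) and NCU02932 (−10.86) for H3G34R, NCU08378 (−9.13) and ncw-5 (−7.68) for set-2 H3G34R, and NCU08378 (−9.09) and NCU09968 (−7.24) for set-2 ash1(Y888F). Differences between tables were not tested, and the values for set-2 ash1(Y888F) rest on another wild type, so they do not rank the genotypes. Derived from the authors' deposited tables for H3G34R and set-2 ash1(Y888F) and centred over genes, the wild types differed by 2.42 for vvd, 2.17 for cry and −4.18 for pho-4. In the libraries themselves pho-4 stood at 16.6 ± 13.2 CPM in set-2 ash1(Y888F) and 2.69 ± 0.475 CPM in set-2 H3G34R (SD, n = 2 each).

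Of 12 clock and light genes, 11, 10 and 7 were lower in the authors' deposited tables for H3G34R, set-2 H3G34R and set-2 ash1(Y888F), and 1, 0 and 0 were higher. Of 15 histone methylation genes, 14, 8 and 1 were higher and 0, 1 and 1 lower in the authors' deposited tables in the same order. Conidiation genes were lower for 9, 6 and 1 of 13 and higher for 1, 3 and 1 in the authors' deposited tables. Plant cell wall and carbon genes were lower for 13, 11 and 1 of 20 and higher for 2, 1 and 5. Proteasome genes were higher for 22, 26 and 0 of 30 and lower for 2, 1 and 0 in the authors' deposited tables. Complex I genes were lower for 18, 2 and 0 of 29 and higher for 6, 9 and 0. The last of each count rests on another wild type than the first 2, so these counts do not compare the genotypes. Standard errors were also larger in that table for each histone gene, though not for every gene with few reads. For hH3 the authors' deposited standard error was 0.215, against 0.0863 in H3G34R and 0.0897 in set-2 H3G34R. Fewer calls there need not mean fewer changes. Derived from the authors' deposited tables and centred over genes, the shared wild type lay above the other by a median log2 value of 1.35 for clock and light and 1.80 for conidiation, and stood at −0.501 for the proteasome. Derived in the same way, H3G34R differed from set-2 ash1(Y888F) by −0.51, −0.192 and −0.348 for these lists. A fall or rise against wild type thus cannot be assigned to the genotype. Between the libraries themselves 19 of 30 proteasome genes were higher in set-2 ash1(Y888F) than in H3G34R.

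Calls of H3G34R and set-2 H3G34R in the authors' deposited tables overlapped for 1639 higher and 1922 lower genes, against 802.1 and 782.8 for independent lists. Fold changes of these tables correlated over 7253 genes with r = 0.708 and a covariance of 1.40. Unchanged groups simulated against 2 shared control libraries gave a mean r of 0.500 and a covariance of 0.0272. That simulation drew controls and groups from the same levels, so it holds no offset between mutants and wild types of other series. The derived wild-type levels behind the tables for H3G34R and set-2 H3G34R were nearly identical, with a median absolute log2 difference of 0.00106, and their controls could not be split. Part or all of the excess over independent lists and over the simulation may thus come from the shared controls. Behind the authors' deposited table for set-2 ash1(Y888F) stood other wild-type levels. They differed from the shared ones, after centring, by a median absolute log2 value of 0.659 and by over 2-fold for 1973 of 6148 genes within the limits on mean count and fold change. Overlaps of that table were 606 higher and 359 lower with set-2 H3G34R, against 256.9 and 161.1 for independent lists, and 425 and 279 with H3G34R, against 334.6 and 189.2. Its fold changes correlated with r = 0.483 with those of set-2 H3G34R and r = 0.0873 with those of H3G34R; all these r are across genes, which are not independent replicates.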

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

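All tests in this part were chosen only after results were seen. In set-2 H3G34R replicate 1, 16.1% of reads lay in no annotated gene, and in the same library 5.32% of reads lay at several places in the genome; they were listed because these reads lie outside the measured genes, a rule that every library meets. The other 5 libraries held 9.16% to 11.6% and 2.27% to 4.09%, so this library was the highest in both shares; the cause was not tested.

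Reads of set-2 in libraries of strains described as deletions were weighed first. An exchange of labels with the H3G34R libraries was weighed by the lowest level of the 6 libraries, 18.3 CPM. If a deletion leaves almost no reads, at least 1 library should have held almost none. The level argues against an exchange in that case only. With an allele that keeps the transcript, set-2 reads cannot show an exchange. RNA of the H3G34R strains mixed into those libraries is argued against too, as 12 of 3289 genes with at least 50 CPM in both H3G34R libraries kept under 1% of that level, the 10th lowest share being 0.898%. An allele that leaves the counted part of the transcript in place could account for the set-2 level of 92.3% of that in H3G34R, but gene counts hold no positions, so this and another meaning of the label cannot be told apart here.

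Fold changes of H3G34R and set-2 ash1(Y888F) were little alike in the authors' deposited tables, with r = −0.0468 over the 6148 genes with derived wild-type levels. Different wild-type libraries behind the tables might be the cause: against the wild type shared by the H3G34R tables r was 0.747, and it was 0.372 against that of the set-2 ash1(Y888F) table. Against 1 wild type r rises by construction, and the values lie on both sides of the r of 0.621 for H3G34R with set-2 H3G34R as deposited, so the test cannot tell. A larger distance of H3G34R from set-2 ash1(Y888F) than from set-2 H3G34R is argued against by the mutant levels themselves, with r = 0.894 against 0.851 across genes, which are not independent replicates.

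The antisense share was higher in the libraries labelled set-2 by 0.487 percentage points. Sense reads taken for antisense by the kit should raise the median share of the 500 genes highest in sense reads as much as the total share. That median moved by −0.115 percentage points in set-2 H3G34R against 0.370 for the total, and by 0.313 in set-2 ash1(Y888F) against 0.620, which argues against such leakage as the whole cause. Reads of overlapping genes are argued against as the whole cause by a remaining difference of 0.218 over genes that share no reads with an opposing gene, where the lowest library labelled set-2 lay at 1.15% and the highest other at 1.07%. Leakage and overlapping genes acting together were not tested. Over genes without shared reads the mean share was 1.35% in set-2 ash1(Y888F) against 1.04% in H3G34R. That rise is about as large as the 0.313 in the median of the 500 highest genes. Both causes together thus remain open for set-2 ash1(Y888F). In set-2 H3G34R the mean share over those genes was 1.16%, while that median moved by −0.115. Genotype and culture or library batch were not separated by the design and cannot be told apart.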

How the results depend on the processing

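No paired analysis was possible because the replicate numbers only name libraries within a genotype. The outermost 25, 50 and 100 genes, genes without reads shared with an opposing gene, the 500 highest genes, the shares without 20 genes and the lists by symbol were chosen after seeing the data. Of 5806 values of 484 gene results under alternatives, 4956 kept direction and side of the threshold, 846 became weaker, 2 stronger and 2 reversed; 213 of the weaker came from glmTreat and 135, 116, 39, 23, 108 and 114 from leaving out H3G34R replicates 1 and 2, set-2 ash1(Y888F) replicates 1 and 2 and set-2 H3G34R replicates 1 and 2, the larger source. In the order set-2 H3G34R minus set-2 ash1(Y888F), set-2 H3G34R minus H3G34R and set-2 ash1(Y888F) minus H3G34R, changed genes numbered 1131, 3079 and 2248 with glmTreat against 1.5-fold, a stricter hypothesis by construction. Leaving out 1 library gave 1388 (without set-2 H3G34R replicate 2) to 3766, 3803 to 5879, and 2754 (without H3G34R replicate 1) to 4565. DESeq2's size factors and test, no filter, both strands and fits of 2 genotypes stayed within 1.5 times. Gene lists past the test numbered 8, 1 and 4 in the main analysis, 15, 14 and 15 with fry mixed, 1, 10 and 8 with fry and 0, 0 and 0 with a correlation estimated per list. With 1 library left out, 2 (without H3G34R replicate 1) to 8 lists passed in the first comparison and 1 in the second. In the last, 4 passed each time, but not always the same ones, as without set-2 ash1(Y888F) replicate 2 histone methylation did not pass and a list that had not passed in the main analysis did. For chromosome ends the odds ratio with the outermost 25 genes was 1.43 for genes higher in the first comparison, no longer past the test (1.34 with the outermost 100, past it), and 0.897 for genes lower in the second, reversed. Antisense genes numbered 1059, 997 and 1166 in a separate fit of genes without shared reads, where fewer genes were tested, and 950 to 1695 in the first comparison with 1 library left out. The difference in antisense share was 0.218 over genes without shared reads, 0.0988 as the median of the 500 highest genes, 0.264 without 20 genes and 0.428 to 0.535 with 1 library left out. With at least 2-fold, 3987 and 2541 genes passed in the authors' deposited tables for H3G34R and set-2 H3G34R. For set-2 in the second comparison leaving out H3G34R replicate 2 gave −0.04194, reversed, and leaving out replicate 1 gave 0.32. For hH3 in the last comparison leaving out set-2 ash1(Y888F) replicate 2 gave 0.05087, reversed, and replicate 1 −0.15. The cause was not tested for any other change. Distances of 100, 200 and 300 kb, the 500 bp rule, lists by product text and a replicate block were not run. With 2 libraries per genotype and 7.52 to 9.83 M sense reads, 2-fold changes were recovered for 49.3% to 58.2% of simulated genes. Far fewer genes changed in those simulations than in the real comparisons, where recovery may differ.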

Other observations

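The test of neighbouring genes in this part was chosen only after results were seen, as were the genes named. In both genotypes labelled set-2, the adjacent genes NCU04706, NCU04707 and NCU04708 had no reads, while in H3G34R they stood at 90.9 ± 0.798, 13.5 ± 1.57 and 9.50 ± 2.80 CPM (SD, n = 2 each). The libraries of a genotype also differed at single genes. The Ku protein gene mus-52 had 2 and 922 sense reads in H3G34R replicates 1 and 2, 0 and 0 in the set-2 ash1(Y888F) libraries and 1 and 2 in the set-2 H3G34R libraries, with 280, 3, 325, 290, 260 and 216 antisense reads in the same order. NCU08378 had 2041 and 0 sense reads in H3G34R replicates 1 and 2, 0 and 0 in the set-2 ash1(Y888F) libraries and 3 and 12 in the set-2 H3G34R libraries. The 2 H3G34R libraries came from different strains, whose backgrounds were not compared, so a fall of this gene against wild type in the authors' deposited tables need not follow the genotype.

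The wild-type levels derived from the authors' deposited tables differed between the tables; the log2 differences here were centred on the median over genes, so they are not ratios of the levels themselves. In the wild type shared by the H3G34R tables of the authors' deposited tables, conidiation genes lay higher than in that of the set-2 ash1(Y888F) table by a median log2 value of 1.80, clock and light genes by 1.35 and plant cell wall and carbon genes by 1.71. Single genes derived from the authors' deposited tables included con-10 at 6.14 and con-8 at 6.32, while mus-51 differed by −2.28. The mean normalised count of con-10 was only 35.05 in the table for set-2 ash1(Y888F).

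A hypothesis formed here was that genes changed at least 4-fold lie beside each other more often than chance placement allows, as they might if chromatin domains changed together. Neighbouring pairs among genes at least 4-fold lower in set-2 H3G34R than in H3G34R numbered 159, against a mean of 42.1 and a highest value of 69 in 100000 random sets (permutation test, p = 1e-05, the smallest possible). The other counts were 119 pairs for genes higher in that comparison (mean 41.4), 78 and 165 for genes higher and lower in set-2 ash1(Y888F) than in H3G34R (means 20.9 and 36.4), and 29 and 34 for genes higher and lower in set-2 H3G34R than in set-2 ash1(Y888F) (means 5.94 and 4.57). Chance placement is argued against by each of these 6 counts, but shared regulation, gene clusters, and segments lost or replaced in a strain were not separated.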
